A study of Mus musculus with 2 samples.

How the data were processed

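MEF2A ChIP-seq was done in CH12.LX cells in 2 biological replicates, numbered 1 and 2 in the labels, from separate biosamples. The deposited files used were 6 peak lists in narrowPeak layout, 5 on mm10 and 1 on mm9. Per the file headers and the texts deposited with them, each replicate has a relaxed list of peaks and background called on its alignments with a control file, a pooled relaxed list was called on both replicates with a control file, and the optimal and conservative IDR sets were made from the pooled list and both replicate lists. The mm9 list was derived from the mm9 alignments of both replicates; no control file is named for it. Peaks were therefore called by the authors both per sample and on pooled samples. The peak caller, the aligner and their versions are not given in the sources used here. The control library was not analysed here.

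The signal value of each peak is as deposited by the authors; its scale is set by each call, so it was compared by rank within a list, and a log2 of it was correlated only across matched peaks. The score columns of the deposited lists were kept as the authors gave them: the scaled score of the IDR sets was not used, and the nominal q-value column, which reaches below 0 (lowest -0.152 in the optimal set) and was therefore treated as a score, served only to break ties. The p column is -1 throughout and was not used. Each of the 3 relaxed lists holds 300000 intervals, a round number that is a limit of the list and not a measure of depth. In the optimal set 96.4% of intervals are 360 bp wide. Read depth is unknown, so no interval here covers sequencing error. The 95% intervals of shares are Wilson intervals and those of folds are computed on the log scale; both cover counting error over peaks or genes only, and neighbouring peaks are not independent.

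The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are 1-based. Peaks were called shared when they overlapped by 1 bp or more. Genes and TSSs on mm10 came from the RefSeq table of GRCm38.p6. That table gives no strand, so strand was looked up by symbol or synonym on the same chromosome in GENCODE vM1, which gave a usable outermost TSS for 20583 of 21900 protein-coding genes (94.0%). Internal TSSs are thus missed on mm10, and the mm9 counts, which use every protein-coding GENCODE vM1 transcript, are given beside several genes for which this mattered. Sequence was held for mm9 (NCBIM37) only. The highest peak end lay within the reference length on each of the 20 chromosomes of the mm9 list, and no coordinates were converted between builds. The builds were joined only by gene symbol: of 6038 genes with an mm9 peak within 10 kb, 5477 (90.7%) also had an optimal peak, against 44.0% of all 20341 genes in both annotations.

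The design had planned motif tests on the optimal set; as mm10 sequence was not used here, the motif results come from the mm9 list. For the same reason the motif and GC parts of the comparisons between IDR sets and between restricted and shared peaks were not made. The TSSs planned were those of all transcripts, and the mm10 results use 1 TSS per gene. Random mm10 positions, 10 per peak, were drawn on the same chromosome between the first and last pooled interval, without leaving out inner assembly gaps. Motif windows ran 50 bp to either side of the summit and were compared with 5 random windows per peak that overlapped no peak and were matched on chromosome and GC content in bins of 2 percent, with a mean GC content of 50.6% in peaks and 50.3% in background. A motif was counted as present when its consensus matched exactly on either strand, so weaker sites were not counted.

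Gene lists (20) and motifs (34, of which 3 were forms of the MEF2 element) were fixed before the data were examined. A gene counted when a summit lay within 10 kb of its TSS, and each list was compared with all other protein-coding genes. All tests of shares were two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over the 20 lists or the 31 other motifs, with a threshold of 0.05. The matched random lists were drawn within 10 deciles of promoter GC content (taken from mm9 by symbol for 98.8% of genes) and 5 quintiles of gene length. With 1 group of 2 samples no test across replicates was possible. Genes named are the nearest genes of the 20 strongest optimal peaks; Mef2a to Mef2d, Hdac4, Hdac5, Hdac7 and Hdac9; in each list up to 4 members with the strongest peak within 10 kb, and every member without a peak where 4 or fewer lacked one; and the nearest genes of the 3 strongest peaks restricted to each replicate. Some genes that these rules select are left out of the text. The motif test was checked on simulated sequence, where it found 100% of planted windows and called 0 of 31 null motifs. The planted sites were drawn from the consensus itself, in random bases of the same composition as the background. The gene list test was checked on 20583 genes with 200 simulated peaks, where it called the planted list and 0 of 19 null lists. These checks cover the code and not how well the backgrounds suit real sequence or the full peak set. Alternatives covered the peak set, signal threshold, each replicate alone, overlap rule, TSS distance, TSS set, motif window and form, and background. Others were added after seeing the data: the mm9 list with GENCODE TSSs, the weakest pooled intervals as background, and the optimal peaks within the strongest part of the pooled list.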

Results

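The series measured where MEF2A, a MADS-box transcription factor that binds an AT-rich DNA element, sat on the genome of CH12.LX cells, a mouse B cell lymphoma line. Chromatin immunoprecipitation with a MEF2A antibody followed by sequencing (ChIP-seq) was done on 2 biological replicates from separate biosamples, which form 1 group. No second condition or factor was part of the series, so the comparisons were between the replicates, between the peak sets, and between the peaks and the rest of the genome. The optimal set of the irreproducible discovery rate (IDR) procedure, which keeps peaks ranked alike in repeated lists, held 31497 peaks on mm10, with a median signal of 34.9 and a range from 6.41 to 535. The signal is the authors' own value per peak and is used only to rank peaks within a list. A separate list on mm9 held 16839 peaks. The files are peak lists, so the read depth of each sample is unknown. All p-values describe lists of peaks or genes and not the spread between cultures.

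The strongest MEF2A peaks lay mostly far from promoters. The peak with the highest signal (535) spanned 43383107 to 43383536 on chromosome 16 (mm10), inside Zbtb20, which encodes a zinc finger repressor; the nearest RefSeq transcription start site (TSS) was that of Tigit, 281788 bp away, as 1 outermost TSS per gene was used on mm10. It ranked first in both replicates. The strongest mm9 peak, measured to the TSSs of all protein-coding transcripts, lay in an intron 19095 bp from a Zbtb20 TSS. The next mm10 peaks lay inside Matn2 (signal 475, chromosome 15, 34336234 to 34336525), 10249 bp upstream of Ccdc9 (467, chromosome 7, 16296919 to 16297230) and inside Rad51b, with Zfp36l1, which encodes an mRNA decay factor, as the nearest TSS (466, chromosome 12, 79840448 to 79840771). Others lay inside Manba (463), upstream of Wfdc21 (457), 202813 bp upstream of Runx1 (452), which encodes a haematopoietic transcription factor, and inside Lyn (444), a kinase of B cell receptor signalling. The remaining peaks of the 20 strongest had Spdl1, St6gal1, Med21, Ddc, Rapgef6, Hdac5, Nrbf2, Dot1l, Ccser2, Edn2, Cysltr2 and Sycp3 as nearest genes by RefSeq TSS, with signals from 399 to 430. The summits given to Ddc, Edn2 and Sycp3 lay inside Grb10, Hivep3 and Gnptab. Among the 20 strongest mm9 peaks, with all transcript TSSs, were intronic peaks with Grb10 (30814 bp), Hivep3 (144835 bp) and St6gal1 (11487 bp, against 77222 bp on mm10) as nearest genes. Of the 20 strongest mm10 peaks, 15 had a summit over 10 kb from a RefSeq TSS and 1 lay within 1 kb, 158 bp upstream of Rapgef6. On mm9, with all transcript TSSs, 2 of the 20 strongest lay within 1 kb of a TSS, near Rapgef6 and Hdac5. Every one of the 20 mm10 peaks ranked 38th or better in replicate 1 and 30th or better in replicate 2.

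Among genes of the MEF2 family and their partners, the class IIa histone deacetylases, Mef2a and Hdac5 carried strong peaks, but the list did not pass the test in the main setting. Within 10 kb of the TSS, 5 of 8 genes had a peak (62.5%, 95% Wilson interval 30.6 to 86.3) against 43.8% of other protein-coding genes (two-sided Fisher's exact test, adjusted exact p = 0.364 over 20 lists). Mef2a itself had 3 peaks. The strongest (signal 378, rank 32, chromosome 7, 67372727 to 67372991, mm10) lay 3587 bp downstream of the RefSeq TSS. Hdac5 had 2 peaks within 10 kb, the stronger at its TSS (325, chromosome 11, 102230075 to 102230329), and a further peak of signal 412 inside the gene 11197 bp from that TSS. With all transcript TSSs on mm9, the strongest Hdac5 peak (rank 19) lay 46 bp from a TSS. The distance of 11197 bp may thus reflect the use of 1 TSS per gene on mm10. Mef2b had 7 peaks (strongest 127), Mef2d 9 (strongest 119) and Hdac7 2 (strongest 40.9). Mef2c, Hdac4 and Hdac9 had none within 10 kb of the outermost RefSeq TSS. On mm9, where the TSSs of all protein-coding GENCODE transcripts were used, Mef2c and Hdac9 had 1 peak each, Hdac4 again had none, and Hdac7 had 3, the strongest of which ranked 55th of 16839. The list passed in 3 of 10 other settings: the mm9 list (7 of 8 genes, adjusted exact p = 0.00285), the stronger 50% of optimal peaks (5 of 8, adjusted exact p = 0.0439) and each peak given to its nearest gene (8 of 8, adjusted exact p = 0.0159).

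B cell gene lists, fixed before the data were examined, had MEF2A peaks more often than other genes. The other genes were not matched on expression or open chromatin, which the series did not measure. Active genes of any kind could show this, and the ribosomal and histone lists, given below, were also raised. A summit lay within 10 kb of the TSS for 23 of 24 B cell identity genes (95.8%, 79.8 to 99.3, adjusted exact p = 3.09e-07), against 43.7% of other genes. The strongest were near Ikzf3 (signal 241), a zinc finger regulator of lymphocytes, Foxo1 (237), Cd22 (220) and Cd79b (214), which encodes a chain of the B cell receptor complex. The member without a peak was Pou2f2, an octamer-binding factor, and it had 4 peaks on mm9 with all transcript TSSs. Of B cell receptor signalling genes, 20 of 21 had a peak (95.2%, 77.3 to 99.2, adjusted exact p = 2.32e-06), strongest near Rasgrp3 (275), Vav1 (172), Pik3ap1 (126) and Blnk (123); Nfatc2 had none on either build. In the germinal centre list 12 of 15 genes had a peak (80%, 54.8 to 93.0, adjusted exact p = 0.0128). Members with strong peaks included Cxcr4 (177), Cxcr5 (114) and Rgs13 (94.0). Mybl1, Gcsam and Bach2 lacked one, although Bach2 had 1 on mm9. For genes of MHC class II presentation the count was 15 of 16 (93.8%, 71.7 to 98.9, adjusted exact p = 9.77e-05), with Cd80 (117), Cd74 (73.7), Ciita (68.4) and H2-DMa (63.3) strongest on mm10 and Rfxap without a peak; on mm9, with all transcript TSSs, Ciita (rank 545) came before Cd80 (rank 2489). This list's call ended when only summits within 1 kb counted (6 of 16 genes, adjusted exact p = 0.613) and with a 50 kb window (adjusted exact p = 0.0589).

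Genes of acute responses were marked in the same way. In the NF-kB list 21 of 22 genes had a peak (95.5%, 78.2 to 99.2, adjusted exact p = 1.24e-06), strongest near Nfkbiz (188), Il10 (174), Rel (165) and Nfkbia (160), and Il6 had none. Among immediate early genes, which respond rapidly to stimulation, 27 of 29 had a peak (93.1%, 78.0 to 98.1, adjusted exact p = 1.38e-07). The strongest lay 1190 bp upstream of Ier2 (314), 25 bp upstream of Jun (308), 239 bp upstream of Klf6 (265) and 8212 bp downstream of the Ier5 TSS (204). Klf2 and Arc had none. The mm9 peak at the Jun promoter held the MEF2 element CTAAAAATAG at 94718937 to 94718946 on chromosome 4, within 1 kb of a TSS, and the Klf6 promoter held the same sequence at 5860479 to 5860488 on chromosome 13.

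Ribosomal, histone, apoptosis, cell cycle and glycolysis genes also had peaks more often than other genes. Peaks lay near 63 of 75 ribosomal protein genes (84.0%, 74.1 to 90.6, adjusted exact p = 7.80e-12), strongest near Rpl35 (346), Rpl23 (114), Rpl23a (104) and Rpl27 (101.3). Of replication-dependent histone genes, 53 of 63 had a peak (84.1%, 73.2 to 91.1, adjusted exact p = 5.50e-10). These genes lie in clusters and share peaks: H2ac6, H4c3 and H2bc4 had the same strongest peak (77.9), followed by that of H2ac7 (48.0). The histone call ended when each peak was given to its nearest gene (adjusted exact p = 0.302) and with the mm9 list (30.6% of 62 genes, adjusted exact p = 0.889). Peaks lay near 14 of 18 genes of the BCL2 family and caspases (77.8%, 54.8 to 91, adjusted exact p = 0.00813), strongest near the pro-apoptotic Bmf (298) and Bbc3 (262) and the anti-apoptotic Bcl2l1 (141) and Mcl1 (126), while Bad, Bik, Hrk and Xiap had none. The cell cycle list had 19 of 24 (79.2%, 59.5 to 90.8, adjusted exact p = 0.00140), with Mcm6 (99.8), Rb1 (88.5), Cdkn2c (65.0) and Mki67 (62.9) strongest. Glycolysis had 13 of 17 (76.5%, 52.7 to 90.4, adjusted exact p = 0.0198), with Pkm (72.9), Gapdh (54.5), Slc2a1 (51.7) and Ldha (47.4) strongest and Hk1, Pgk1, Pgam1 and Ldhb without a peak, although Hk1 had 1 on mm9. Against 10000 random lists matched on promoter GC content and gene length, the calls of the BCL2 (adjusted permutation p = 0.158), cell cycle (0.0604) and glycolysis (0.125) lists were lost in a two-sided permutation test. The glycolysis call was also lost with the stronger 50% of peaks (adjusted exact p = 0.0694), within 1 kb (0.0758), within 50 kb (0.144) and on mm9 (0.241). The cell cycle call was also lost within 1 kb (adjusted exact p = 0.230) and on mm9 (0.0596), and the BCL2 call within 50 kb (adjusted exact p = 0.115).

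No list of genes of other tissues or cell types was called as having peaks more often than other genes. The intervals of the muscle and T cell lists are wide and do not exclude a higher share. Olfactory receptor genes had peaks less often than other genes, at 24 of 1099 (2.18%, 1.47 to 3.23, against 46.1%, adjusted exact p = 5.58e-237). Neighbouring genes can share peaks or lack them together, so this p-value and interval count as independent genes that may not be. Random lists matched on promoter GC content and gene length had peaks at 8.13% of genes, against 2.21% of the 1088 receptor genes that could be matched. Their strongest peaks were near Olfr314 (82.9), Olfr16 (68.8), Olfr175 (54.3) and Olfr750 (48.3). For striated muscle, a tissue in which MEF2 factors are well studied, 20 of 40 genes had a peak (50%, 35.2 to 64.8, adjusted exact p = 0.453), with values of 243 near Hspb7, 209 near Tnnt2, 128 near Myom1 and 117 near Tnni2. Values were 12 of 22 for T cell genes (54.5%, 34.7 to 73.1, adjusted exact p = 0.434), with Lck (234.1), Ctla4 (208) and Cd4 (107) among the strongest, and 8 of 21 for myeloid genes (adjusted exact p = 0.665), with Cd68 (57.8), Csf1r (33.8), Fcgr1 (31.3) and Siglec1 (27.9) strongest. Neuronal genes had 5 of 23 (adjusted exact p = 0.0511), strongest near Camk2a (103), Gad1 (41.1), Tubb3 (32.2) and Dlg4 (31.9). Hepatocyte genes had 5 of 22 (adjusted exact p = 0.0698), strongest near F9 (89.9), G6pc (47.6), Pck1 (31.8) and Apoa2 (28.0). Calls in other settings, all towards fewer genes with a peak, came in 3 of 10 for myeloid and neuronal genes and in 1 for muscle and hepatocyte genes.

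Plasma cell genes (10 of 14, adjusted exact p = 0.0698) and lymphocyte migration genes (11 of 15, adjusted exact p = 0.0511) missed the threshold in the main setting but not in most others. Migration genes had peaks more often in 7 of 10 other settings, among them replicate 2 alone (14 of 15 genes, adjusted exact p = 0.000246), replicate 1 alone (14 of 15, adjusted exact p = 0.000317) and the conservative set (12 of 15, adjusted exact p = 0.00450). Plasma cell genes did so in 6 of 10, among them the conservative set (adjusted exact p = 0.0387) and replicate 2 alone (adjusted exact p = 0.0206), but not replicate 1 alone (adjusted exact p = 0.0802). Against the matched random lists neither passed in a two-sided permutation test (adjusted permutation p = 0.115 for plasma cell and 0.124 for migration genes). Migration genes also missed the threshold within 50 kb (adjusted exact p = 0.0805) and by nearest gene (0.0513). Plasma cell genes also missed it within 1 kb (adjusted exact p = 0.300) and within 50 kb (0.265). The plasma cell list was led by Mzb1 (167), Txndc5 (145), Jchain (115) and Edem1 (66.4). Its members without a peak were Prdm1, Sdc1, Creb3l2 and Fkbp11, of which Prdm1 had 4 peaks on mm9. The migration list was led by Cxcr4 (177), Ccr7 (137), Ccr6 (131) and Itga4 (127), and Itgb7, Itgb2 and Klf2 were among those with none. It shared Cxcr4, Cxcr5 and S1pr2 with the germinal centre list and Klf2 with the immediate early list, so these calls are not independent.

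**Figure D1:**
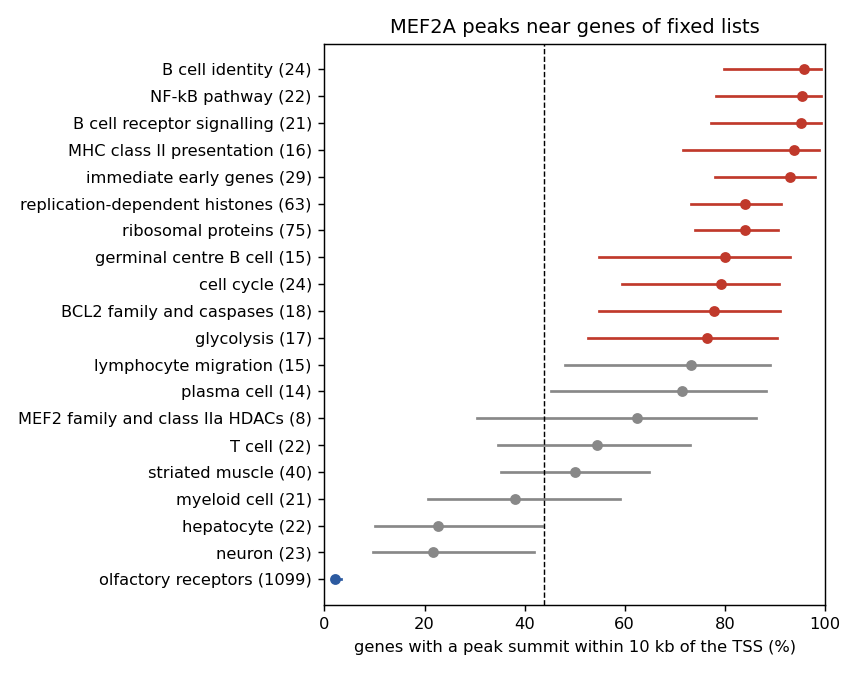
Share of genes in each of 20 fixed lists with an optimal-set summit within 10 kb of the TSS (percent, x axis; the number of genes is in parentheses). Points are shares and lines are 95% Wilson intervals; red lists had peaks more often than other genes at an adjusted p under 0.05, blue less often, and grey lists did not pass; the dashed line is the share of all protein-coding genes (43.8%).

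The MEF2 element was concentrated at peak summits. Its consensus YTAWWWWTAR occurred within 50 bp of the summit in 1201 of 16839 mm9 peaks (7.13%, 6.75 to 7.53), against 0.803% of random windows matched on chromosome and GC content, an 8.88-fold difference (95% interval 8.10 to 9.75). The share was 14.2% (13.1 to 15.4) in the strongest quintile of signal and 3.71% (3.12 to 4.4) in the weakest, a difference of 10.5 percentage points (two-sided Fisher's exact test, p = 3.38e-54). CTAAAAATAG, counted together with its reverse complement CTATTTTTAG, was the commonest form, at 212 peaks. Most peaks carried no consensus match, and 4 of the 20 strongest on mm9 carried one. The strongest mm9 peak within 10 kb of an Hdac5 TSS (chromosome 11, 102080116 to 102080481, within 1 kb of a GENCODE TSS) held CTATAAATAG at 102080297 to 102080306, and the Mef2a peak (chromosome 7, 74517579 to 74517913, within 1 kb of a TSS) held CTATTTTTAG at 74517737 to 74517746. Intronic peaks with the element included those at Bmf (CTAAATATAG, chromosome 2, 118366753 to 118366762), Bbc3 (CTATTTATAG, chromosome 7, 16899429 to 16899438), Pou2f2 (CTAAATATAG, chromosome 7, 25914791 to 25914800) and Hdac7 (CTATTTTTAA, chromosome 15, 97655707 to 97655716). The strongest mm9 peak, in an intron of Zbtb20, held TTATTTATAG at 43383438 to 43383447 on chromosome 16. The fold rose to 41.9 for the strict form CTAWWWWTAG and fell to 4.41 for the core TAWWWWTA, 4.47 against flanking windows, which were richer in AT, 5.05 within 100 bp of the summit and 3.13 over whole intervals.

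**Figure D2:**
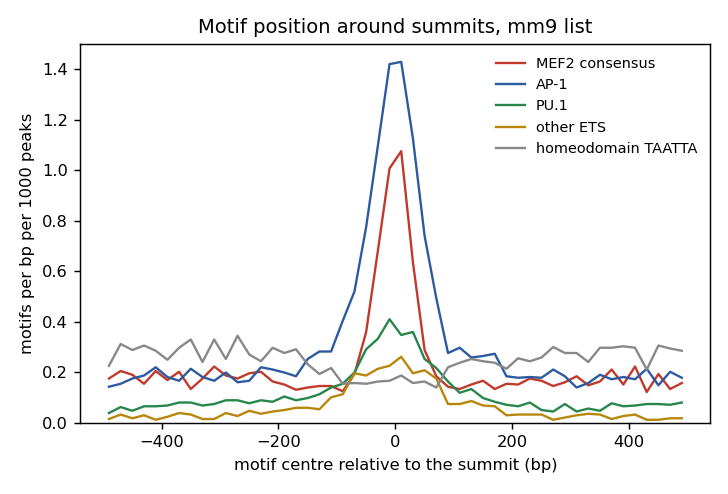
Positions of motif centres relative to the summits of 16839 mm9 peaks (x axis, bp, in bins of 20 bp; y axis, motifs per bp per 1000 peaks). The MEF2 consensus reached 1.07 in the bin from 0 to 20 bp and 0.175 in the bin starting at -500 bp.

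Elements of many other transcription factors, those of B cell factors among them, were also frequent at these summits. Of 31 other motifs, 23 were more frequent than in GC-matched windows and 3 less frequent (Benjamini-Hochberg adjusted p under 0.05). These windows were not matched on open chromatin or distance to a TSS, so open sites in general could show this. At distal peaks alone 20 were more frequent. There the fold of ETS sites other than PU.1 and SpiB was 4.21 (3.13 to 5.67). Over all peaks, the AP-1 element occurred at 10.7% (10.2 to 11.1), 6.84-fold over background (6.38 to 7.33). The NF-kB element was at 7.0% (6.63 to 7.40), 4.93-fold (4.55 to 5.33). The composite element of ETS and IRF factors was at 4.39% (5.43-fold, 4.90 to 6.02), RUNX at 3.99% (4.59-fold, 4.14 to 5.09), PU.1 and SpiB at 3.24% (4.86-fold, 4.32 to 5.46) and the octamer at 3.12% (6.30-fold, 5.54 to 7.15). Other ETS sites were at 1.98% (10.5-fold, 8.66 to 12.6), EBF1 at 1.21% (4.71-fold, 3.89 to 5.71) and CTCF at 1.32% (14.8-fold, 11.4 to 19.2). The NF-Y (0.697-fold, 0.638 to 0.763), YY1 (0.810-fold, 0.705 to 0.930) and GATA (0.660-fold, 0.567 to 0.769) elements were less frequent over all peaks. Forkhead (1.00-fold, 0.850 to 1.18) and homeodomain (1.11-fold, 0.971 to 1.26) elements did not pass the test. Against flanking windows, which were not GC-matched (46.4% GC against 50.6% in peaks), the GATA call remained (0.558-fold), the NF-Y (0.989-fold, adjusted exact p = 0.878) and YY1 (1.16-fold, adjusted exact p = 0.0882) calls were lost, and the forkhead (0.763-fold, adjusted exact p = 0.00298) and homeodomain (0.573-fold, adjusted exact p = 3.24e-17) elements were less frequent. At distal peaks alone NF-Y (0.593-fold), YY1 (0.570-fold) and GATA (0.643-fold) were less frequent. The 3499 promoter peaks without the MEF2 consensus were compared with windows matched on GC content and TSS-distance class. There NF-Y (1.32-fold, adjusted exact p = 0.00201) and YY1 (2.92-fold, adjusted exact p = 5.43e-16) were more frequent. GATA did not pass there (0.760-fold, adjusted exact p = 0.372).

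Peaks were concentrated at promoters relative to the genome, although most lay elsewhere and the strongest were the least promoter-bound. On mm10, 21.7% of peaks (21.2 to 22.1) had a summit within 1 kb of a protein-coding TSS against 1.58% of random positions, a 13.7-fold difference (13.2 to 14.2). A further 20.1% lay 1 to 10 kb away, 44.6% lay 10 to 100 kb away and 13.6% lay over 100 kb away, against 12.7%, 42.6% and 43.1% of random positions. The share within 1 kb was 10.8% (10.1 to 11.6) in the strongest signal quintile and 28.4% (27.3 to 29.6) in the weakest (two-sided Fisher's exact test, p = 6.04e-141). On mm9, where exons and introns were annotated, 38.8% of summits lay in introns, 36.7% were intergenic against 56.9% of random positions, 0.855% were in coding exons and 1.06% in 3′ UTRs. The promoter fold was 22.5 with a 500 bp window, 4.33 with a 5 kb window, 7.53 against the 100000 weakest intervals of the pooled list and 8.44 for the mm9 list with GENCODE TSSs.

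At promoters the MEF2 consensus was rarer than at distal sites. It occurred at 115 of 3614 mm9 peaks within 1 kb of a TSS (3.18%, 2.66 to 3.81) and at 1086 of 13225 distal peaks (8.21%, 7.76 to 8.69; odds ratio 0.367, two-sided Fisher's exact test, p = 1.59e-29). In the strongest signal quintile the promoter share was 16.0% (12.3 to 20.5) and the distal share 14.0% (12.8 to 15.3), with overlapping intervals. GC-matched windows held the element less often for promoter peaks (0.234%) than for distal peaks (0.957%).

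**Figure D3:**
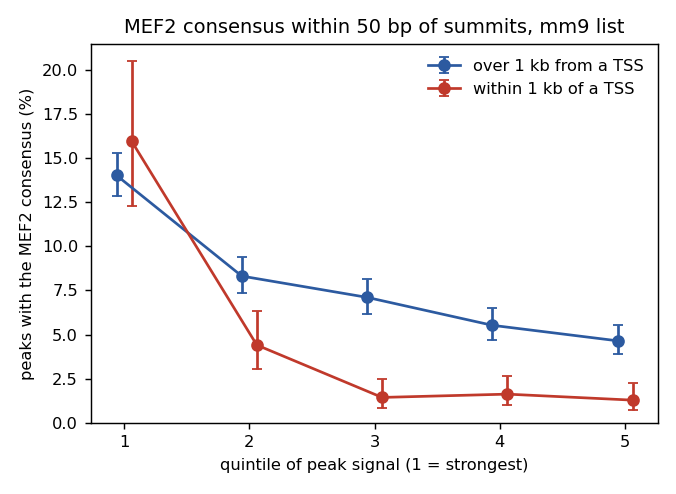
Share of mm9 peaks with the MEF2 consensus within 50 bp of the summit (percent, y axis) in each quintile of peak signal (x axis, 1 is the strongest), for 3614 peaks within 1 kb of a TSS (red) and 13225 farther away (blue). Bars are 95% Wilson intervals; the promoter and distal shares were 16.0% and 14.0% in the strongest quintile and 1.28% and 4.64% in the weakest.

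The replicates shared most strong sites. Of the 100, 1000, 5000 and 31497 strongest peaks of replicate 1, 70.0%, 80.4%, 74.3% and 67.6% overlapped a peak of the same rank range in replicate 2 by 1 bp or more. The optimal set was itself made from both replicate lists, so values on it describe the chosen peaks and do not test agreement. Of its peaks, 64.6% were overlapped by the 31497 strongest peaks of both replicates, 97.6% by the whole lists of both and 35.7% by the 15748 strongest of both. Across 30739 optimal peaks matched in both replicates, Spearman's rho of the signal was 0.577 and Pearson's r of its log2 was 0.663.

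**Figure D4:**
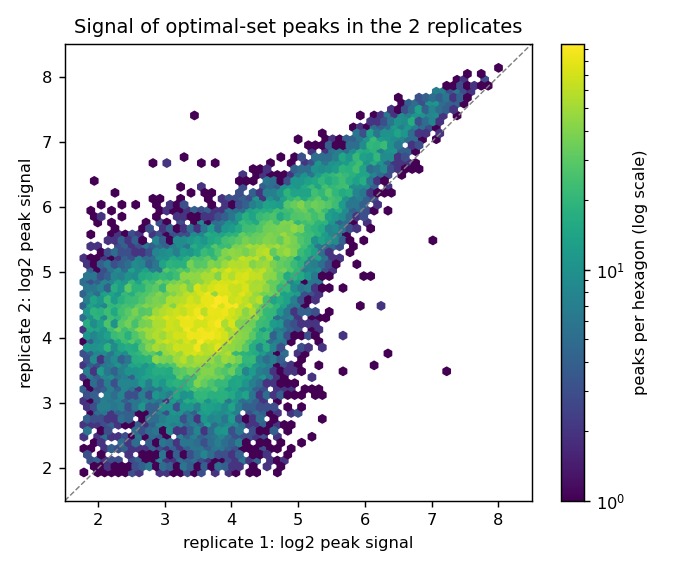
Log2 of the authors' peak signal in replicate 1 (x axis) and replicate 2 (y axis) at 30739 optimal-set peaks matched in both; colour is the number of peaks per hexagon on a log scale and the dashed line marks equal values. Spearman's rho was 0.577, and the signal scale differed between the lists, with a median log2 difference of 0.74 (replicate 2 minus replicate 1).

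Peaks restricted to 1 replicate came mostly from the weaker part of each list. Among the 31497 strongest peaks, 32.4% of those in replicate 1 and 34.1% of those in replicate 2 had no overlap in the strongest of the other, but in the strongest 7874 peaks these shares were 2.71% and 3.90%. Peaks near this rank limit can pass it in 1 replicate only, so the gradient follows in part from the limit. Of the restricted peaks, 84.7% in replicate 1 and 79.2% in replicate 2 were present in the whole list of the other. The strongest restricted to replicate 1 lay inside Srgap3 (signal 84.2, chromosome 6, 112861702 to 112861835, mm10) and 82 bp from the TSS of Mnt (41.8), a repressor of the MYC network. The Srgap3 peak was absent from the whole list of replicate 2, while the Mnt peak had rank 33187 there. Those of replicate 2 lay outside any gene, 390198 bp from the nearest TSS, that of Ebf1 (79.6, chromosome 11, 45008123 to 45008472), inside Pla2g4a (70.8) and inside Akap1 (65.4). The peak nearest to Ebf1 was absent from the whole list of replicate 1. The Pla2g4a and Akap1 peaks had ranks 32231 and 31821 there, just past the limit of 31497. Summits within 1 kb of a TSS made up 23.8% of peaks restricted to replicate 1 against 20.9% of shared ones (odds ratio 1.18, two-sided Fisher's exact test, p = 4.71e-09), and 18.1% of those restricted to replicate 2 against 20.6% (odds ratio 0.851, p = 9.08e-08). The first call was lost when restricted meant absent from the whole other list (odds ratio 1.01, exact p = 0.822), and its odds ratio was 2.19 among the 15748 strongest peaks of each (30.3% against 16.5%, exact p = 1.03e-81). The second turned in that same comparison (odds ratio 1.29, exact p = 1.28e-08).

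The conservative IDR set held 28217 peaks, and 85.4% of them overlapped an optimal peak. The 7362 optimal peaks that did not overlap it were weaker, with a median signal of 23.7 against 40.9 for those in both. Their share within 1 kb of a TSS was 23.4% (22.4 to 24.4) against 21.1% (20.6 to 21.7), with an odds ratio of 1.14 (two-sided Fisher's exact test, p = 5.31e-05).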

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

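The alternatives that used the mm9 list with GENCODE TSSs, the weakest pooled intervals as background or the optimal peaks within the strongest 31497 of the pooled list were chosen after seeing the data; the others were fixed before the data were examined. Over 49 alternatives for 11 results, 39 kept the direction and the side of the threshold or stayed within the limits of a count. The promoter fold stayed above 1 in every alternative run, from 4.33 to 22.5 (12.6 without replicate 1 and 13.8 without replicate 2), the MEF2 consensus fold from 3.13 to 41.9, and the quintile difference from 9.94 to 15.8 points. The peak number was 15748 for the stronger 50% by signal, by construction. The replicate overlap was 53.4% with summits within 100 bp, 55.8% with reciprocal overlap of 50%, 97.6% with the whole lists and 35.7% with the 15748 strongest of each, as the construction of each rule sets. Spearman's rho was 0.632 for the conservative set, 0.599 with the highest overlapping signal and 0.591 for the stronger 50% by signal. The odds ratio of promoter location was 1.01 (exact p = 0.822) for replicate 1 peaks absent from the whole other list, which leaves 1562 peaks, rose to 2.19 for replicate 1 and turned to 1.29 for replicate 2 with the 15748 strongest peaks of each; the cause was not tested. Of 12 called gene lists, 7 kept their call in all 10 other settings: B cell identity, B cell receptor signalling, germinal centre, NF-kB, immediate early, ribosomal and olfactory. The number called ranged from 9 to 15 (14 without each replicate). The number of enriched other motifs ranged from 20 to 23. The MEF2 motif, its quintiles and the other motifs were not run for the conservative set or either replicate, as mm10 sequence was not used here. No paired analysis was possible because the series has 1 group. Depth is unknown, so what it limits was not measured.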

Other observations

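The comparison of motifs among distal peaks was chosen only after results were seen, and the tests on chromosome 11 were written after its peak density had been seen but before their own values. Genes with the most optimal peaks within 10 kb of the TSS were Grap (15 peaks), Il10 (13), Il21r (11), Zfp36 (11) and Junb (11), named here after their values were seen. Tnfrsf13b, which encodes a receptor for B cell survival factors, and Ebf1 each had 9.

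Distal mm9 peaks with and without the MEF2 consensus differed in their other elements. The NF-kB element was at 8.20% of 12139 distal peaks without the consensus and 3.41% of 1086 with it (odds ratio 0.395, two-sided Fisher's exact test, adjusted exact p = 8.68e-09 over 31 motifs). The AP-1 element was at 13.1% and 9.48% (adjusted exact p = 0.00325), the PU.1 element at 3.74% and 1.93% (adjusted exact p = 0.00595) and the EBF1 element at 1.51% and 0.368% (adjusted exact p = 0.00366). The octamer was at 3.66% and 3.50% (adjusted exact p = 1). Elements more frequent with the consensus included the TATA box (2.16% without it and 18.5% with it, adjusted exact p = 3.34e-97) and the homeodomain element (1.45% and 6.08%, adjusted exact p = 9.55e-18), whose AT-rich sequences can lie on the same bases as the consensus. GC content was not matched between these groups of peaks.

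Chromosome 11 held 30.5 optimal peaks per Mb, against a median of 11.6 and a highest value of 17.2, on chromosome 16, among the other 18 autosomes; chromosome X held 2.13. Gene density may contribute: chromosome 11 had 2.29 peaks per protein-coding gene, within the range of the others (0.877 to 2.60) but above their median of 1.48. A similar gene density on chromosome 7, 13.5 genes per Mb against 13.3, came with far fewer peaks, 11.9 per Mb. More copies of chromosome 11 DNA in these cells may contribute, as a hypothesis: the 100000 weakest pooled intervals were also densest there, at 77.0 per Mb against 33.2 to 59.1 on the other autosomes, and 21 of its 23 bins of 5 Mb lay above the autosomal median in peak density. The bins count the same peaks, so most lying above the median follows largely from the high density itself. They ranged from 14 to 364 peaks. Weak intervals can also follow strong binding and open chromatin, so these values do not separate copy number from regulatory activity, and the design gives no group for a biological explanation. The density was 32.0 in replicate 1, 29.8 in replicate 2 and 17.3 in the mm9 list, where the highest other autosome had 10.02.

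The lower share of the MEF2 consensus at promoters was weighed against 3 explanations. Weaker signal at promoters is argued against as the whole cause, since the promoter share lay below the distal share beyond the Wilson intervals in 4 of 5 signal quintiles. GC content goes in the direction of the pattern: GC-matched windows held the element at 0.234% for promoter peaks and 0.957% for distal peaks. Relative to these windows the promoter share was not lower. The fold was 13.6 (9.57 to 19.3) at promoters and 8.58 (7.79 to 9.44) at distal peaks. A higher fold at promoters is an outcome that neither of the stated predictions covered, so how much GC content explains stays open. Binding next to other factors may contribute, since promoter peaks without the consensus held the ETS element 10.3-fold more often than matched promoter windows (7.20% against 0.697%), although any set of active promoters could show this. No biological explanation was tested against a group, as the design has 1.

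The optimal set included 1118 peaks (3.55%) beyond rank 100000 of the pooled list, although the set holds 31497. Overlap with a stronger neighbour is consistent with this: 86.4% of them (84.3 to 88.3) overlapped a stronger optimal peak, against 1.65% of the optimal peaks within the strongest 31497. For the other 152 the cause stays open. Merging overlapping intervals left 28754 regions.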
